A study of Mus musculus with 5 samples.

How the data were processed

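RNA was measured in 5 mouse co-cultures, each hybridised to 1 one-colour oligonucleotide array with 12488 probe sets. Per the labels, haematopoietic cells were cultured for 6 days on ST2-T stromal cells with dexamethasone and the active form of vitamin D, and each dish was harvested whole, so that every array holds total RNA of both the haematopoietic and the stromal cells. The groups were taken from the sample titles. They are Fos+/+ spleen, Fos-/- spleen, Fos+/+ bone marrow, Fos-/- spleen cells infected with a virus called deltaNFAT in the labels, and Fos-/- spleen cells infected with a virus carrying green fluorescent protein (GFP). There was 1 array per group and no replicate.

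The authors deposited 1 intensity per probe set and array, on a linear scale. The software and the steps that made these values are not given in the sources used here. The values themselves show a scaling and a background subtraction, because the mean without the lowest and highest 2% was 100.1 in every array and 20.3 to 22.4% of the values of an array were at or below 0. All columns of the table matched a sample title.

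Each array was multiplied so that its mean without the lowest and highest 2% was equal across arrays, which moved no array visibly since the deposited values were already scaled. The floor was the 40th percentile of all scaled values, an intensity of 19.8. Values under it were set to it, and log2 was taken after that. Between 58.3 and 62.3% of the probe sets of an array lay above the floor. Gene names came from the platform annotation. Of the probe sets, 10855 carried 1 gene symbol, 396 several and 1237 none, and only those with 1 symbol were named. A match by gene identifier to a RefSeq gene table (assembly GRCm38.p6, used for names alone) succeeded for 10839 probe sets and changed 0 symbols. The 66 control probe sets stayed out of gene counts. A gene with several probe sets was represented by the brightest over the 5 arrays, which left 8251 genes, 6409 of them above the floor in at least 1 array.

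Since there are no replicates, no test was run and no p-value, standard deviation or standard error can be given. A gene was counted as higher or lower when the ratio of 2 arrays reached 2-fold and the brighter array reached 2 times the floor (39.6). Where the dimmer array lay at or under the floor the fold is a lower bound, written "at least". The 4 comparisons were Fos+/+ over Fos-/- spleen, deltaNFAT over GFP virus, Fos+/+ bone marrow over Fos+/+ spleen, and GFP virus over no virus in Fos-/- spleen. Overlaps of gene counts were taken between ratios that share no array, over genes whose brighter array reached 2 times the floor in both ratios, beside the overlap of independent lists and with an exact (Clopper-Pearson) 95% interval of the share, which treats genes as independent although they are not.

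Before the data were examined, 26 gene lists of cell types and pathways were fixed. The median log2 ratio of a list, over members above the floor in at least 1 array, was placed among the medians of 10000 random lists of the same size matched on deciles of mean log2 intensity. A list was said to stand apart at a percentile of 2.5 or less or 97.5 or more, which describes these arrays only, because genes of one list do not vary independently. The rule for named genes was fixed at the same time. It took, in each of the first 2 comparisons, the 10 largest folds each way among genes above the floor in both arrays with the brighter array at 4 times the floor (79.2) or more, and the 5 brightest genes each way among those at the floor in the dimmer array. For the other comparisons these numbers were 5 and 3. It also took Fos, Nfatc1, every osteoclast list member on the array, and up to 4 members of each other list with the largest log2 ratios and the same brightness. Any gene named outside this rule is said to be so.

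The procedure was tested on data simulated from the Fos-/- spleen array with added noise. For Fos+/+ over Fos-/- spleen, it recovered 91 of 100 genes changed 3-fold and 100 of 100 changed 6-fold, and it counted 1.73% of 8051 unchanged genes. The changed genes were drawn from those reading 79.2 or more in the Fos-/- spleen array, so this recovery does not cover dimmer genes. In the simulated comparison of deltaNFAT with GFP the procedure counted 166 of 8251 unchanged genes (2.01%), where the real arrays gave 178 higher and 130 lower. The noise there was an assumption, since no replicate array gives the real one. Its standard deviation was 0.15 on the natural log scale and 10 in intensity, added to values not below 0. The 1st percentile of the real arrays lay between -133 and -77.6, so the real noise near the floor may be larger. The counts of unchanged genes may then be too low. The number of arrays limits the precision of every value.

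Alternatives planned beforehand were the values as deposited, quantile normalization, other floors, the mean of all probe sets of a gene, leaving out probe sets whose identifier carries a letter suffix of any kind, a 3-fold rule, the other Fos-/- spleen array as control, random lists without matching, and all list members. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for the figures.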

Results

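The arrays compared co-cultures in which haematopoietic cells meet the conditions that form osteoclasts, the cells that resorb bone. The Fos gene encodes a subunit of the transcription factor AP-1, and the design asks what its loss does to spleen-derived co-cultures and what a deltaNFAT virus does in cells without Fos. NFAT proteins are transcription factors, and the labels do not describe the deltaNFAT construct further. The 5 groups were Fos+/+ spleen, Fos-/- spleen, Fos+/+ bone marrow, Fos-/- spleen with deltaNFAT virus and Fos-/- spleen with GFP virus, the last serving as the virus control. Each group had 1 array, so every fold below describes a pair of arrays and has no replicate error. Of 12488 probe sets, between 7282 (Fos+/+ spleen) and 7782 (Fos+/+ bone marrow) lay above the floor intensity of 19.8. The ratio of the 3-prime to the 5-prime control probe set ran from 1.02 to 1.31 for Actb and from 0.77 to 0.85 for Gapdh. Across genes above the floor, the log2 values of the deltaNFAT and GFP arrays correlated at r = 0.96 and those of the Fos+/+ and Fos-/- spleen arrays at r = 0.93, over genes that are not independent replicates.

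Fos itself did not settle the labels. Its brighter probe set read 848 in Fos+/+ spleen, 614 in Fos+/+ bone marrow, 426 in Fos-/- spleen, 581 with deltaNFAT and 607 with GFP, and the other was under the floor in every array. The stromal cells of each dish carry their own Fos, and where the probe sequences lie relative to the deleted part is not given in the sources used here, so these values check nothing. Nfatc1, a transcription factor that drives osteoclast differentiation, read 751 in Fos+/+ spleen, 325 in Fos+/+ bone marrow, 23.5 in Fos-/- spleen, 82.7 with deltaNFAT and 23.4 with GFP. Whether its probe set also reads a transcript made from the virus is unknown.

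Osteoclast genes were among the largest differences between Fos+/+ and Fos-/- spleen co-cultures. Ctsk, the collagen-degrading protease cathepsin K, read 2862 against 61.3 and was 46.7-fold higher in Fos+/+ spleen. Car2, a carbonic anhydrase that supplies protons for bone resorption, was at least 49.0-fold higher, and Nfatc1 was 32.0-fold higher. Acp5, the tartrate-resistant acid phosphatase used to stain osteoclasts, was 8.31-fold higher, and Calcr, the calcitonin receptor, at least 17.0-fold higher. Of the 17 measured members of the osteoclast list, 13 were at least 2-fold higher, 0 lower and 4 neither. The list's median log2 ratio was 2.43, above all 10000 matched random lists.

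The remaining osteoclast calls were the sodium-proton exchanger Slc9b2 (at least 18.0-fold), the V-ATPase subunits Tcirg1 (6.55-fold) and Atp6v1c1 (2.39-fold), the creatine kinase Ckb (6.22-fold), the myosin Myo1d (5.40-fold), the gelatinase Mmp9 (3.59-fold), the integrin chain Itgav (2.57-fold) and the RANK receptor Tnfrsf11a (2.37-fold). Clcn7 at 1.71-fold, Traf6 at 1.49-fold, Fosl1 at 1.02-fold and Itgb3, dim in both arrays, did not reach 2-fold. Src was under the floor in all 5 arrays.

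**Figure D1:**
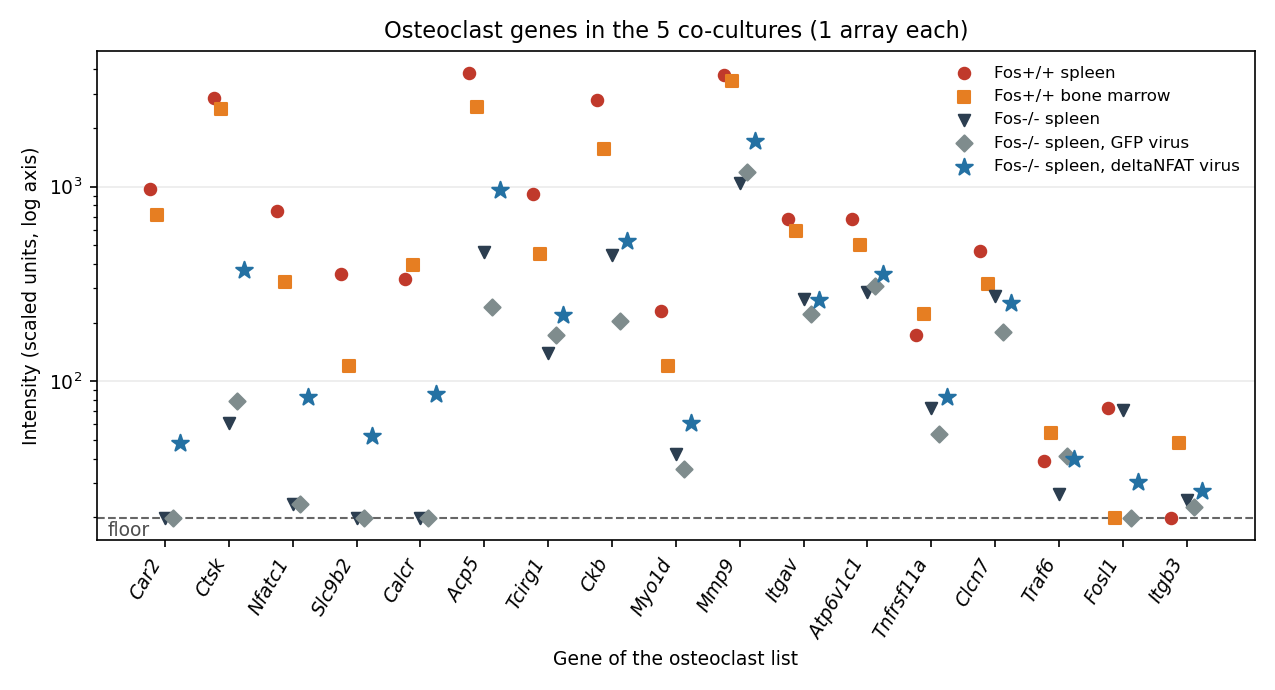
Intensity of each measured osteoclast list gene in the 5 co-cultures, on a log axis with values under the floor of 19.8 (dashed line) drawn at it. Each point is 1 array and there are no error bars. For Ctsk the points read 2862 in Fos+/+ spleen, 2495 in Fos+/+ bone marrow, 372 with deltaNFAT, 79.3 with GFP and 61.3 in Fos-/- spleen.

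Subunits of the proton pump were also higher with Fos, and lists of energy metabolism shifted in their medians. In the V-ATPase list 7 of 14 measured subunits passed 2-fold, 0 were lower and the median log2 ratio was 0.95, with Atp6v1d at 3.17-fold and Atp6v1b2 at 3.12-fold; 2 of these genes are in the osteoclast list as well. Oxidative phosphorylation genes shifted by a smaller amount, with a median of 0.42, 3 of 34 higher and 1 lower, among them the succinate dehydrogenase subunit Sdhb (2.36-fold) and cytochrome c, Cycs (2.90-fold). Glycolysis genes had a median of 0.41 although 0 of 14 passed 2-fold upward and Hk2 was 2.76-fold lower. Each of these 3 lists lay at percentile 99.82 of the random lists or above. The list of lysosomal enzymes and membrane proteins did not stand apart, with a median of -0.00, 1 of 30 higher and 2 lower.

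Proliferation genes were higher in the Fos+/+ spleen culture. Of 27 measured, 10 passed 2-fold and 0 were lower, with a median log2 ratio of 0.52 at percentile 100. Examples were the mitotic kinase Aurka (at least 4.27-fold), the survivin gene Birc5 (3.38-fold), Cdc20 (2.98-fold) and the cyclin Ccna2 (2.92-fold). The RANK, M-CSF and NF-kB signalling list had a median of 0.16 at percentile 98.8, with 2 of 22 higher and 0 lower. Outside the lists, the 10 largest folds included the lysosomal membrane protein gene Gpr137b (19.6-fold) and its near copy Gpr137b-ps (7.34-fold), which the probe sets may not tell apart. Others were the semaphorin Sema4d (15.1-fold), the ubiquitin ligase Rnf19b (9.10-fold), Pstpip1 (8.13-fold), the surface glycoprotein Cd200 (7.0-fold) and the DNA methyltransferase Dnmt3a (6.87-fold). Fam102a was at least 16.7-fold and the matrix proteoglycan decorin, Dcn, at least 16.1-fold higher. The adaptor Blnk was 6.33-fold higher, the lipase Lpl 3.71-fold and the mast cell protease Mcpt1 4.42-fold. The podosome, actin and integrin list did not stand apart (median 0.03), yet Rac2 (3.56-fold), Capg (2.81-fold) and Anxa2 (2.04-fold) were among its 4 higher members.

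Medians of the neutrophil and macrophage lists were lower in Fos+/+ than in Fos-/- spleen. In the neutrophil and granule list 5 of 14 were at least 2-fold lower and 0 higher, with a median log2 ratio of -0.96, below all random lists. The neutrophil granule protein Ngp was 8.79-fold lower, the calprotectin subunit S100a9 3.10-fold and lactoferrin, Ltf, 2.42-fold. Among macrophage genes 4 of 26 were lower and 2 higher, with a median of -0.35 at percentile 0.07, within the random range at a noise floor of 98.8 chosen after the data were seen. The scavenger receptor Marco was 7.08-fold lower, the mannose receptor Mrc1 3.69-fold and Aif1 3.24-fold, whereas the myeloid transcription factor Spi1 was 2.03-fold higher (under 2-fold after quantile normalization). Stromal fibroblast and matrix genes had a median of -0.27 at percentile 0.06, with 4 of 37 lower and 2 higher. Tagln was 2.23-fold, Vcam1 2.52-fold and Igfbp4 3.97-fold lower, the last not passing 2-fold in the mean of its probe sets or with unsuffixed ones.

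Lymphoid and antigen presentation lists held few measured genes. In the T and NK cell list 3 of 7 were lower and 1 higher (median -0.56, percentile 1.67), with Cd4 6.69-fold lower. Zap70 was 6.32-fold lower, but its probe set without a letter suffix gave a log2 ratio of 0.10. The MHC class II and dendritic cell list had 1 of 10 lower and 0 higher (median -0.40, percentile 1.27), the 1 being H2-DMa at no less than 6.71-fold. Both lists lost their place apart when all members or only unsuffixed probe sets were used. Other large folds downward were Gm1673 (6.78-fold), the secreted ribonuclease Rnase4 (6.25-fold), the transporter Abcc3 (5.63-fold), the adducin Add1 (5.23-fold), the formyl peptide receptor Fpr2 (5.19-fold) and the transcription factor Tef (4.94-fold). Stard10 was at least 11.5-fold lower, Gkap1 at least 8.92-fold, the mitochondrial phosphate carrier Slc25a3 at least 7.85-fold, the NADPH oxidase subunit Ncf1 at least 7.27-fold and Tnni1 at least 6.96-fold. Gkap1 did not pass with unsuffixed probe sets. Apoe was 2.32-fold lower (not passing in the mean of its probe sets) and the chemokine Ccl6 3.18-fold lower, while the chemokine Ccl9 was 2.34-fold higher.

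In total, 324 genes were at least 2-fold higher and 321 lower in Fos+/+ than in Fos-/- spleen, of 4997 bright enough to pass, and 66 and 32 of them reached 4-fold. Of the 76 named genes that passed, 65 kept their call under all alternatives apart from the changed floors and 46 under these as well, 34 of the 44 higher genes and 12 of the 32 lower ones. Aurka, Cycs, Hk2, Ltf and Ccl6 were among those lost at the floor of 65.1, and Hk2 did not pass in the mean of its probe sets either. The counts depend on the floor: at an intensity floor of 65.1 (the 60th percentile) they were 139 and 125. A second ratio of Fos+/+ to Fos-/- cells, bone marrow over GFP spleen, shares no array with this one but differs from it in tissue and virus. Of 250 genes higher in the first ratio and bright enough in both, 103 were higher in the second as well (41.2%, exact 95% interval 35.0 to 47.6), against 19.8 for independent lists. Downward the overlap was 63 of 277 against 14.6. The osteoclast list had 13 of 17 genes higher in that second ratio too, with a median log2 ratio of 1.76. The V-ATPase list (median 0.49, 1 of 14 higher) and the macrophage list (-0.25, 4 of 26 lower) kept their direction there. The neutrophil and granule list went the other way, with a median of 0.70, 4 of 14 higher and 0 lower. Proliferation (median 1.12), oxidative phosphorylation (0.34) and RANK, M-CSF and NF-kB signalling (0.30) stood apart upward there as well. The glycolysis (0.20) and stromal (-0.04) lists kept their sign but did not stand apart. The T and NK cell (0.67) and MHC class II and dendritic cell (0.27) medians changed sign and did not stand apart either.

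With deltaNFAT virus, part of the osteoclast genes were higher than with GFP virus in Fos-/- spleen cells. Ctsk read 372 against 79.3 and was 4.69-fold higher, Acp5 read 964 against 239 and was 4.03-fold higher, and Ckb read 524 against 203 and was 2.58-fold higher. Without virus Acp5 read 462 and Ckb 448, so Ckb with deltaNFAT lay within 2-fold of the array without virus. Whether its GFP value was low by noise or through the virus was not tested. Calcr was at least 4.36-fold, Slc9b2 at least 2.64-fold and Car2 at least 2.44-fold higher, and Nfatc1 was 3.53-fold higher. In the list, 7 of 17 measured genes passed 2-fold, 0 were lower, 10 were neither, and the median log2 ratio was 0.62, above all random lists. It fell to 0.34 at the floor of 65.1 and to 0.22 at the noise floor of 98.8, still apart. The calls of Calcr, Slc9b2, Car2 and Nfatc1 rest on deltaNFAT intensities between 48.4 and 86.4 and were lost at the floor of 65.1, while those of Ctsk, Acp5 and Ckb were kept.

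These levels stayed under those of the Fos+/+ spleen culture. Over the 13 osteoclast genes that passed between Fos+/+ and Fos-/- spleen, the deltaNFAT array read a median of 25.1% of the Fos+/+ spleen value (range 4.99 to 51.7%), with values under the floor set to it. The corresponding medians were 7.28% with GFP, 15.3% in Fos-/- spleen without virus and 73.2% in Fos+/+ bone marrow. These genes were chosen as at least 2-fold higher in Fos+/+ than in Fos-/- spleen without virus. That choice by itself lowers all such shares, and it limits the share of Fos-/- spleen without virus in advance. The other measured members read 138% (Itgb3), 102% (Traf6), 54.1% (Clcn7) and 41.8% (Fosl1) with deltaNFAT. Over deltaNFAT, the Fos+/+ bone marrow array had 11 of 17 list members higher and 0 lower, with a median log2 ratio of 1.18. Mmp9 was 1.44-fold, Myo1d 1.72-fold, Tnfrsf11a 1.54-fold, Tcirg1 1.27-fold and Itgav 1.18-fold higher with deltaNFAT than with GFP and did not pass. Of the V-ATPase list 0 of 14 passed, with a median of 0.03 at percentile 88.6, and of the oxidative phosphorylation list 0 of 34, with a median of 0.02. Proliferation genes had a median of 0.16 with 1 of 27 higher, a place apart that was lost at the floor of 65.1.

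**Figure D2:**
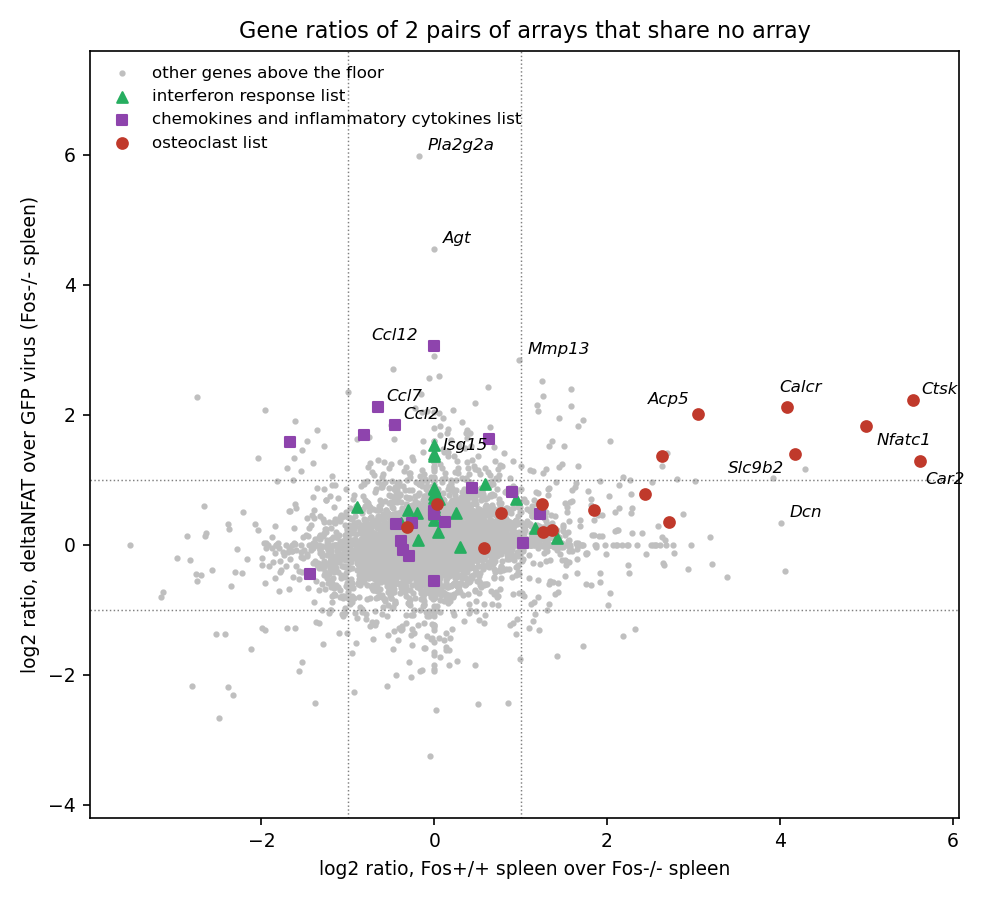
The log2 ratio of deltaNFAT over GFP virus (vertical) against that of Fos+/+ over Fos-/- spleen (horizontal), 1 point per gene above the floor, with dotted lines at 2-fold. Colours mark 3 gene lists, and values under the floor were set to it. Ctsk lies at 5.54 and 2.23, and Pla2g2a at -0.17 and 5.98.

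The largest folds with deltaNFAT lay outside the osteoclast list. The secreted phospholipase Pla2g2a read 1247 with deltaNFAT and between 17.1 and 23.6 in the other arrays, at least 63.0-fold over GFP. Angiotensinogen, Agt, read 463 and was under the floor elsewhere, at least 23.4-fold over GFP. The collagenase Mmp13 was 7.19-fold and the stromelysin Mmp3 at least 7.48-fold higher, and the acute phase gene Saa3 4.41-fold. In the list of chemokines and inflammatory cytokines 6 of 20 were higher and 0 lower, with a median log2 ratio of 0.47 at percentile 100, or 0.04 over all members including those under the floor. Ccl12 was at least 8.33-fold, Ccl7 4.35-fold, Ccl2 3.59-fold and Ccl8 3.10-fold higher, all of them attractants of monocytes. In GFP over no virus 3 of 20 members of this list were also higher and 0 lower (median -0.02), among them Ccl2 and Ccl7. Interferon response genes had a median of 0.58 at percentile 100, with 3 of 25 higher and 0 lower. These were Ifit1 (2.89-fold), Ifit3 (2.62-fold) and Isg15 (2.57-fold). The labels do not give the doses of the 2 viruses.

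The T and NK cell (median 0.55, 1 of 7 higher), cholesterol synthesis (0.22, 1 of 13), glycolysis (0.14, 0 of 14) and stromal (0.05, 2 of 37) lists also stood apart upward, but each lost this under at least 1 alternative. Among calls of single list members, the MHC class II invariant chain Cd74 was 3.57-fold, the metallothionein Mt2 2.86-fold, the Fc receptor Fcgr2b 2.38-fold and the calcineurin regulator Rcan1 2.17-fold higher with deltaNFAT. Rcan1 read 209 with deltaNFAT, 96.6 with GFP and 201 in Fos-/- spleen without virus, and Mt2 read 1585, 554 and 1907. Both genes with deltaNFAT thus lay within 2-fold of the array without virus. Whether their GFP values were low by noise or through the virus was not tested. The neutrophil and granule list had a median of -0.37, below all random lists, with 0 of 14 passing 2-fold, Ngp being 1.66-fold lower. Genes such as Fam20c (5.71-fold), Pigs (4.32-fold), 2210010C04Rik (3.89-fold), Hyal2 (3.80-fold), Zfp358 (3.72-fold) and Oxt (at least 6.51-fold) also passed. For Oxt the deltaNFAT array read 129, Fos-/- spleen without virus 153 and the GFP array was under the floor, and for Pigs the values were 110, 123 and 25.4. Zfp358 and 2210010C04Rik likewise read higher without virus (117 and 229) than with deltaNFAT (101 and 160). The largest folds downward were Abcc3 (6.36-fold), Foxl1 (5.48-fold), Pmm1 (4.78-fold), the cadherin Cdh11 (3.83-fold), the ribosomal protein gene Rps29 (3.82-fold), Crygd (3.51-fold), Stmn2 (3.50-fold), Fcer2a (3.38-fold) and Glod4 (3.32-fold). Nup85 was 3.46-fold lower, but its probe set without a suffix gave a log2 ratio of 0.10. The homeobox gene Hoxa4 was at least 9.48-fold, Sh2d2a at least 5.84-fold, Phf1 and the acid lipase Lipa each at least 5.39-fold and Ubn1 at least 4.95-fold lower. In the mean of their probe sets Hyal2, Rps29, Crygd and Hoxa4 did not pass 2-fold, nor did Hoxa4 with unsuffixed ones.

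Altogether 178 genes were higher and 130 lower with deltaNFAT than with GFP, of 5032 bright enough. At the floor of 65.1 the counts were 37 and 21. Of the 47 named genes that passed, 42 kept their call apart from the changed floors and 14 under these as well. All 14 were among the 32 higher genes, while 0 of the 15 lower ones were kept under every alternative and 12 were lost at the floor of 65.1, as were Ifit3, Zfp358, Oxt and Pigs of the higher ones. Of the 178 higher genes 61 also passed over Fos-/- spleen without virus, and for 73 the GFP array was at least 2-fold below it. Of the 130 lower genes 73 also passed over it. Arrays simulated without any change gave 166 calls in this comparison, under an assumed noise that may be too small. Of 227 genes higher in Fos+/+ than in Fos-/- spleen and bright enough in both ratios, 33 were also higher with deltaNFAT (14.5%, exact 95% interval 10.2 to 19.8), where independent lists would share 6.52. Downward 25 of 262 were shared against 5.88. Opposite calls were also above this baseline, with 9 genes higher in Fos+/+ spleen and lower with deltaNFAT against 5.09, and 15 the other way against 7.52. Across 6409 genes the log2 ratios correlated at Pearson r = 0.19 and Spearman rho = 0.21. The 324 genes higher in Fos+/+ spleen had a median log2 ratio of 0.12 for deltaNFAT over GFP and of 0.49 for Fos+/+ bone marrow over deltaNFAT.

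Neutrophil genes were higher in bone marrow than in spleen co-cultures of Fos+/+ cells. Ngp read 1835 in bone marrow and 61.5 in spleen and was 29.8-fold higher, S100a9 was 13.3-fold, Ltf 7.65-fold and Lcn2 6.89-fold higher. Of 14 measured genes of the neutrophil and granule list, 12 were higher and 0 lower, with a median log2 ratio of 2.39. The virus arrays, from Fos-/- spleen cells, were above Fos+/+ spleen as well, with list medians of 1.94 for GFP and 1.51 for deltaNFAT and 9 of 14 higher in each. Over GFP the bone marrow median was 0.70 with 4 of 14 higher, and over deltaNFAT 1.08 with 8 of 14. S100a9 read 1791 in bone marrow and 1524 with GFP. Myeloperoxidase, Mpo, was at least 12.3-fold higher with the brighter probe set but did not pass with the unsuffixed one. Macrophage genes had 4 of 26 higher and 0 lower (median 0.16, percentile 95.6), including Mrc1 (10.3-fold), the scavenger receptor Msr1 (5.89-fold) and the oxidase subunit Cybb (4.15-fold). The matrix gene Ogn was 17.9-fold higher, Macf1 10.1-fold, and the chromatin genes Smc4 and Dek at least 12.1-fold and 11.1-fold. All of these macrophage, matrix and chromatin genes, with Macf1, Mpo and S100a9, are among 225 genes that were at least 2-fold higher in the bone marrow, deltaNFAT and GFP arrays than in both uninfected spleen arrays, so they do not mark bone marrow alone. Mrc1 read 596 in bone marrow, 1140 with deltaNFAT and 1045 with GFP, and the macrophage list had a median of -0.25 for bone marrow over GFP, with 0 of 26 higher and 4 lower.

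Osteoclast genes were near or under the spleen level in bone marrow. Ctsk was 1.15-fold, Mmp9 1.07-fold, Car2 1.35-fold and Acp5 1.49-fold lower, none of which passed, and Calcr was 1.17-fold higher. Nfatc1 (2.31-fold), Slc9b2 (2.97-fold), Tcirg1 (2.02-fold) and Fosl1 (at least 3.68-fold) were lower, Itgb3 was at least 2.43-fold higher, and the list's median was -0.45 at percentile 0.565. The median lay within the random range after quantile normalization, where Tcirg1 did not pass either, and Fosl1 and Itgb3 were lost at the floor of 65.1. Lower medians were also found for the AP-1 and NFAT family (-0.52, 4 of 13 lower, Jun 3.45-fold and Fosl2 3.13-fold, both lost at the floor of 65.1) and for oxidative phosphorylation (-0.35, 3 of 34 lower, 1 higher). The V-ATPase (-0.38), glycolysis (-0.41) and vitamin D response (-0.51) lists stood apart downward too, but each lost this under at least 2 alternatives. Fam102a (13.0-fold), the receptor Notch3 (10.3-fold), Nkiras2 (6.57-fold), Bcar1 (5.90-fold) and Krt86 (5.55-fold) had the largest folds downward, and Smarcb1, Arfgap2 and Hyal2 were at least 14.5-fold, 13.2-fold and 9.84-fold lower.

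In total 696 genes were higher and 380 lower in bone marrow than in spleen, of 5291 bright enough, so that 64.7% of the calls were higher. After quantile normalization the counts were 523 and 497, or 51.3%. Of the 57 named genes that passed, 44 kept their call apart from the changed floors and 25 under these as well. Of 578 genes higher here and bright enough in both ratios, 322 were also higher in GFP over no virus (55.7%, exact 95% interval 51.6 to 59.8), a ratio of other arrays, tissues and genotypes, where independent lists would share 54.4. Without the genes shared in direction with that ratio, a count chosen after the data were seen, 374 genes were higher.

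GFP virus against no virus in Fos-/- spleen cells separated interferon response genes. Of 25 measured, 14 were higher with GFP virus and 0 lower, with a median log2 ratio of 1.22 at percentile 100. At the floor of 65.1 the median fell to 0.16, at percentile 99.3. Ifi204 was 11.7-fold, Ifi202b at least 10.3-fold, Isg15 at least 7.20-fold and Iigp1 at least 5.50-fold higher. Ifi204 and Ifi202b belong to a family of similar sequences and were also higher in bone marrow than in Fos+/+ spleen without virus, reading 210 and 164 in bone marrow against 60.1 and 19.9, although Ifi204 did not pass there in the mean of its probe sets. Isg15 and Iigp1 were under the floor in bone marrow. The methyltransferase Inmt was 58.9-fold higher, with 1277 in the GFP array, 730 with deltaNFAT and at most 21.7 in the arrays without virus. The immunoglobulin gene segment Igkv6-23 was 16.7-fold higher, whereas Ighm was 2.97-fold higher with its brighter probe set, probe sets without a suffix giving a log2 ratio of -0.37.

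Neutrophil genes were higher in the GFP array than in the array without virus, with 5 of 14 higher, 0 lower and a median of 0.83 at percentile 100. S100a9 was 3.66-fold and Chil3 2.20-fold higher. Mpo at least 4.02-fold higher had a log2 ratio of -0.35 with the unsuffixed probe set. Proliferation genes had a median of -0.36 at percentile 0.61, with 5 of 27 lower and 0 higher, Cenpa being 2.47-fold lower, and the MHC class II and dendritic cell list one of -0.49, with 3 of 10 lower and 1 higher. Both places apart were lost at the floor of 65.1. Osteoclast genes had a median of -0.01 at percentile 70.5, and 2 of 17 were lower, Ckb (2.21-fold) and Fosl1 (at least 3.61-fold). The macrophage genes Cybb (5.13-fold), Mrc1 (4.88-fold) and Msr1 (4.47-fold) were higher, as were Ogn (16.8-fold), the angiopoietin Angpt1 (15.8-fold), the topoisomerase Top1 (at least 20.2-fold), Sec62 (at least 15.2-fold) and Dek (at least 10.5-fold). These 8 genes and all 3 neutrophil genes named here, S100a9, Chil3 and Mpo, are among the 225 higher in bone marrow as well. In uninfected bone marrow and with GFP, Dek read 220 and 207, Msr1 299 and 295, Cybb 299 and 407, and Ogn 1111 and 1667, so these genes do not mark the virus arrays alone. Psmg3 (6.84-fold, under 2-fold with unsuffixed probe sets), 2210010C04Rik (5.57-fold), Ramp2 (5.17-fold), Arfgap2 (4.87-fold) and the receptor Il6ra (4.85-fold) were lower, and Stard10 and Krtap5-1 at least 11.5-fold and 9.44-fold.

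Altogether 528 genes were higher and 361 lower with GFP virus, of 5113 bright enough, and 206 were higher without the genes shared in direction with bone marrow over spleen. Of the 55 named genes that passed, 41 kept their call apart from the changed floors and 27 under these as well, with Iigp1, Il6ra, Cenpa and Fosl1 among those lost at the floor of 65.1. Both this ratio and that of bone marrow over spleen set one of the arrays of bone marrow, deltaNFAT and GFP against one of the uninfected spleen arrays. All 6 hybridisation controls above the floor, of bacterial or phage sequence, read higher in each of these 3 arrays than in each of the 2 uninfected spleen arrays. The ratios of means ran from 1.13 to 1.51. The Fos+/+ to Fos-/- spleen ratio and the deltaNFAT to GFP ratio each lie within one of these sets of arrays. Osteoclast levels of the virus and bone marrow arrays given as shares of the Fos+/+ spleen value cross the sets. So do values without virus set beside those with deltaNFAT and GFP, as for Ckb, Rcan1 and Mt2.

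**Figure D3:**
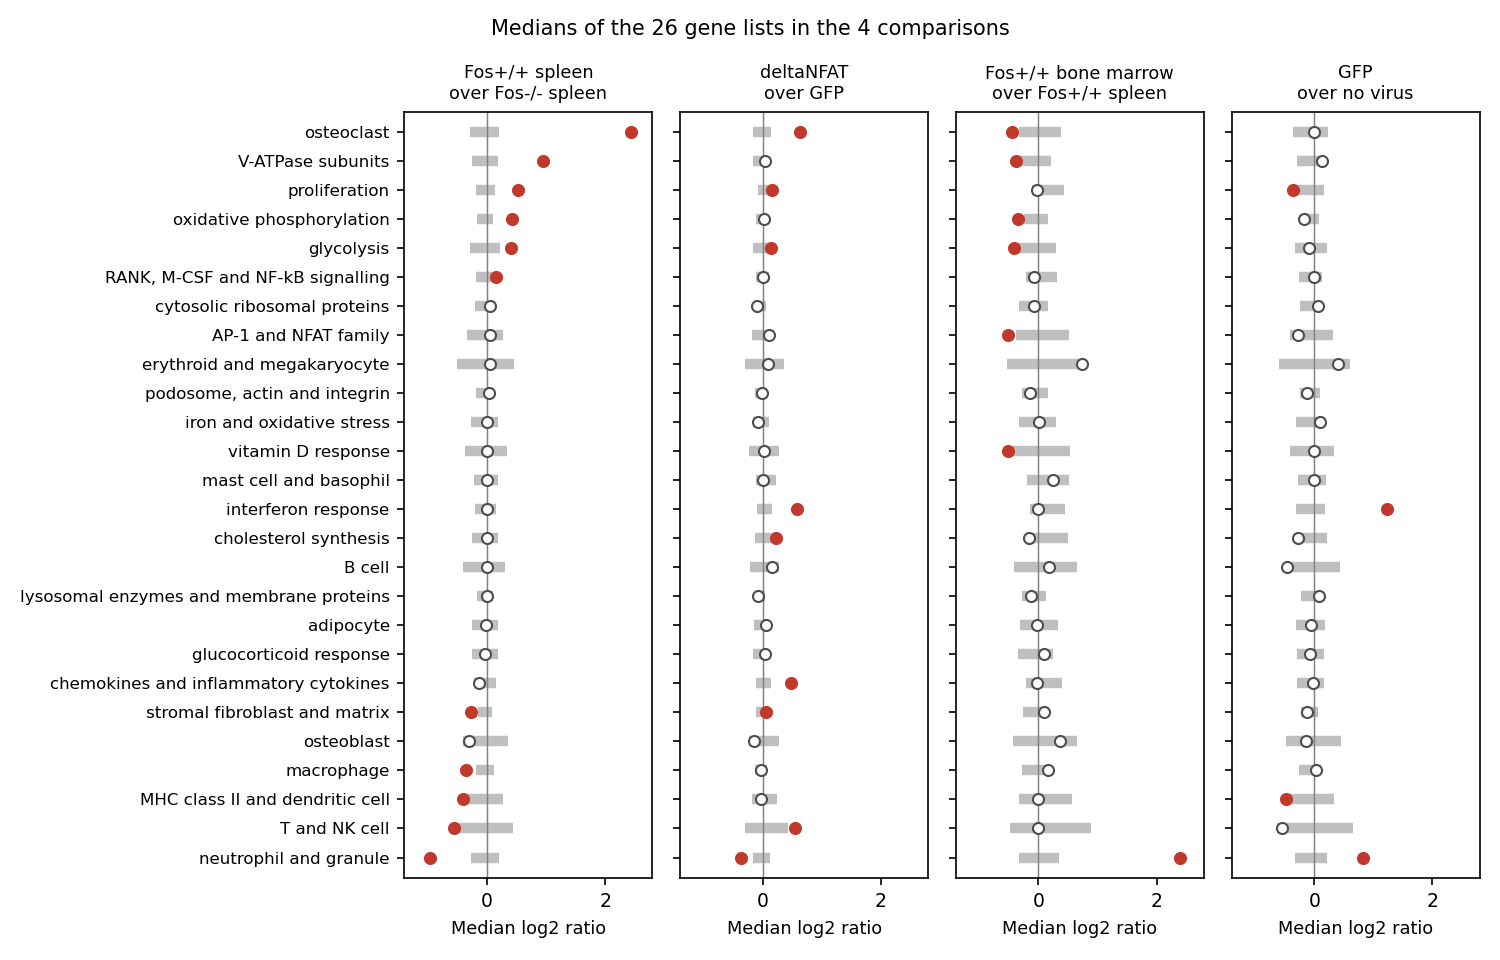
Median log2 ratio of each of the 26 gene lists in the 4 comparisons. Grey bars span the central 95% of matched random lists, and filled points lie outside them. The osteoclast median is 2.43 for Fos+/+ over Fos-/- spleen and 0.62 for deltaNFAT over GFP, and the interferon median is 1.22 for GFP over no virus.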

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

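The alternatives with the 30th percentile floor, the noise floor and without shared genes were chosen after seeing the data, and the others beforehand. Floors at the 20th percentile could not be run because that percentile is -1.20, below 0. No replicate could be left out, and no paired analysis was possible because each group has 1 array. Of the counts, shares, correlations and the Fos and Nfatc1 ratios of Fos+/+ over Fos-/- spleen, 75 values stayed within their margin and 41 moved. The margin was 1.5 times for a count, and the same direction and side of 2-fold for the 2 genes. All ratios of these 2 genes were among the 75. Of the medians of 26 lists in 4 comparisons, 31 stood apart, and 17 of these did so under every alternative. Over all lists 831 values kept their side of the percentile limits, 34 lost a place apart and 23 gained one. Of the values for named genes 3207 kept their side of 2-fold, 207 lost a call, 18 gained one and 8 reversed.

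In the order Fos+/+ over Fos-/- spleen, deltaNFAT over GFP, bone marrow over spleen, and GFP over no virus, the floor at the 60th percentile gave 139 genes higher and 125 lower, 37 and 21, 264 and 146, and 235 and 106. The noise floor of 98.8 gave 97 and 67, 20 and 9, 157 and 86, and 156 and 51. A 3-fold rule gave 111 and 86, 62 and 35, 261 and 125, and 213 and 102. With the floor at the 30th percentile the counts were 510 and 509 and then 377 and 256, with 574 lower for bone marrow and 566 lower for GFP. A raised floor removes dim genes and a stricter rule small folds by construction. With GFP as the control, Fos+/+ spleen had 581 genes higher and 732 lower, and with the array without virus as control deltaNFAT had 569 higher and 345 lower, ratios that cross the 2 sets of arrays. Without shared genes 374 were higher for bone marrow and 206 for GFP.

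The share of genes higher in Fos+/+ spleen that were also higher with deltaNFAT was 9.86% at the 60th percentile floor and 8.70% at the noise floor. The correlation of these ratios across genes was 0.24 at the 60th percentile floor, 0.16 at the 30th and 0.25 at the noise floor. With unsuffixed probe sets alone the log2 ratio reversed to 0.28 for Atp5d and 0.60 for Cox4i1 in bone marrow over spleen, to 0.10 for Zap70 in Fos+/+ over Fos-/- spleen, to 0.10 for Nup85 in deltaNFAT over GFP, and to -0.37 for Ighm, -0.35 for Mpo and 0.20 for Fbln1 in GFP over no virus. The mean of all probe sets reversed Man2b1 to 0.0103 in Fos+/+ over Fos-/- spleen. The cause of these reversals is that other probe sets of the gene were read.

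Signal over background limits the calls. Of the 178 genes higher with deltaNFAT, 80 had the GFP array at the floor, and of the 324 higher in Fos+/+ spleen, 106 had the Fos-/- array there. Among called genes with a further bright probe set, all further ones passed the same way for 25 of 50 in Fos+/+ over Fos-/- spleen, 4 of 19 in deltaNFAT over GFP, 62 of 111 in bone marrow over spleen and 44 of 85 in GFP over no virus. In the same order, at least 1 further probe set passed the opposite way for 3, 2, 8 and 7 of these genes.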

Other observations

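All explanations below were tested after the patterns had been seen. Few genes followed the 3 arrays with the higher osteoclast levels. At 2-fold, 9 genes were higher in both Fos+/+ arrays and in the deltaNFAT array than in both other Fos-/- arrays: Acp5, Calcr, Car2, Ctsk, Nfatc1, Sema4d, Slc9b2, Cdca8 and Upk2. The last 2 were named after their values were seen. The split with Fos-/- spleen and Fos+/+ bone marrow higher held 12 genes, so the number 9 does not stand out. The 3 arrays were picked for their osteoclast levels, so osteoclast genes among the 9 are no separate support. Higher in both Fos+/+ arrays than in all 3 Fos-/- arrays were 49 genes, among them the proliferation genes Aurka and Birc5 and the matrix gene Dcn, which read 320 and 321 in the Fos+/+ arrays, 24.9 with deltaNFAT and was under the floor in the other arrays. In the opposite direction there were 23, including Marco and Fpr2.

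The largest of the 20 directed splits of 2 arrays against 3 was not one of genotype. At 2-fold, 225 genes were higher in the bone marrow, deltaNFAT and GFP arrays than in both uninfected spleen arrays, and the highest other split held 49. Values near the floor are argued against as the whole source, since 61 genes were left at the noise floor of 98.8 against 19 in the highest other split. RNA degradation stays open, because 0 of the 2 control genes, Actb and Gapdh, had 3-prime to 5-prime ratios that separated the sets but 2 genes in 5 arrays are too few to decide. Preparation or hybridisation of the arrays in 2 sets stays open and may be a source. The same sets were separated by 6 of 6 hybridisation control probe sets, where 0.6 would be by chance if these were independent. They are not, being the 3-prime and 5-prime probe sets of BioC, BioDn and CreX alone. No biological explanation was tested, as the labels give nothing that these 3 cultures share.

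Genes higher with deltaNFAT than in each of the 4 other arrays numbered 32, against 71 for Fos+/+ spleen, 55 for bone marrow, 34 for Fos-/- spleen and 10 for GFP, so at this floor their number alone does not stand out among the 5 arrays. They included Pla2g2a, Agt, Mmp13, Mmp3, Saa3 and 5 members of the chemokine list, Ccl2, Ccl7, Ccl8, Ccl12 and Ccl3 (the last named after its values were seen). Some were also higher with GFP than without virus in Fos-/- spleen, a ratio that crosses the 2 sets of arrays. Among these were Mmp13 (293 against 106), Ccl2 (193 against 70.1) and Ccl7 (82.9 against 31.1), whereas Pla2g2a, Agt and Ccl3 were not higher there. Noise that is independent between genes is argued against as the whole source, since 0 of 10000 random draws of as many genes held 5 members of any of the 26 lists and the most was 3. Noise shared by related sequences stays open, because with related names counted once 587 of 10000 draws held as many as these genes. A 2-fold excess of stromal RNA in that culture is argued against by the stromal list's median log2 ratio of 0.0473 over GFP. A smaller excess stays open, because this median stood apart upward at percentile 98.1, with 21 of 37 members raised. Values near the floor are argued against as the whole source by the 10 genes left at the noise floor of 98.8. For the 22 genes lost there values near the floor stay open. At that floor Fos+/+ spleen alone kept 24, bone marrow 6, Fos-/- spleen 6 and GFP 0. The deltaNFAT and GFP arrays correlated most closely (r = 0.96), and a gene raised alike in both counts for neither. Between these 2 arrays, deltaNFAT had the larger count at both floors. A response to the deltaNFAT virus stays open as well, since 1 culture cannot part it from noise or from any other difference between the dishes.

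Interferon response genes were higher in both virus arrays than in each of the 3 uninfected arrays. The list as a whole had a median log2 ratio of 0 for bone marrow over Fos+/+ spleen, 2 of 25 members being higher and 2 lower. Members under the floor in both arrays have a ratio of 0, so this median cannot show a difference between the 2 sets in them. Of 13 members at least 2-fold higher in both virus arrays than in both uninfected spleen arrays, 9 were also 2-fold higher in both than in bone marrow. Bone marrow shares the set of the virus arrays, which argues against the 2 sets as the whole source for these 9. For the other 4 the 2 sets stay open, and Ifi204 and Ifi202b of these were higher in bone marrow than in both uninfected spleen arrays. Virus infection stays open and may account for the pattern. The lowest of the 6 median ratios of a virus over an uninfected array was 1.01 and the highest 1.76. These values restate the pattern and cannot test its cause. Handling of the infected cells other than the virus itself was not tested and stays open. The higher interferon values with deltaNFAT than with GFP could also come from differing virus doses, which the labels do not give.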
